A study of Mus musculus with 9 samples.

How the data were processed

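Total RNA from mouse liver (strain C57BL/6) was isolated with TRIzol and treated with DNase, and samples with an RNA integrity number of 8 or higher were used, per the labels' protocols. Stranded total RNA libraries were made after depletion of ribosomal RNA (TruSeq), per the same protocols. The submitters' processing notes list bcl2fastq, FastQC, STAR, featureCounts and edgeR, without versions, and the genome build mm10. The annotation that STAR used is not given in the sources used here. The deposited files used here are 9 tables of splice junctions, 1 per library, with 9 columns in the layout of STAR's junction output and no header. Their deposited values are counts of uniquely mapped and of multi-mapped reads crossing each junction, not normalized, together with the longest overhang of a read in bases, 38 at most. How multi-mapped reads were counted is not given in the sources used here. Tables of reads per gene were not used here.

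Groups (WT, YAP, YAP_Lsd1ko) and replicate numbers were taken from the sample titles and genotype labels, with 3 libraries per group. Uniquely mapped junction reads per library were 7927071, 7174989 and 8557006 in WT, 8729659, 7877050 and 8162416 in YAP, and 8317912, 6910297 and 9925154 in YAP_Lsd1ko. Junctions were matched by position to the introns of GENCODE M21 (GRCm38), with the strand that STAR gives to the junction. Of 289955 junctions read in any library, 150261 belonged to exactly 1 annotated gene and were summed per gene, which gave 16012 genes with reads. A read that crosses several junctions is counted at each of them, so the counts are not numbers of molecules. Genes without an intron, 1344 of 22028 protein-coding genes, were not measured, and 1702 junctions annotated to several genes were left out of gene counts. Unannotated junctions took 0.83 to 1.00% of junction reads.

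Genes were tested with edgeR 4.0.16 (R 4.3.3) in 1 quasi-likelihood fit with robust dispersions over all 9 libraries, after filterByExpr, which kept 10897 genes, and TMM scaling. Adjusted p-values are Benjamini-Hochberg values per comparison with a threshold of 0.05. An SE of a log2 fold change was calculated back from the test, as its absolute value divided by the square root of the quasi-likelihood F statistic. Where a group had 0 reads, the fold is given against a floor of 3 reads over the group, and where it had 1 to 3 reads as a read ratio with its 95% counting interval. Floors and intervals cover counting error only. The gene lists, 24 in number, were fixed before the data were examined: YAP targets, Hippo components, polyamine metabolism and hypusination, the LSD1 complex, cell cycle, biliary and progenitor, mature hepatocyte, pericentral, periportal, bile acid, fatty acid and sterol synthesis, fatty acid oxidation, acute phase, stellate, macrophage, neutrophil, lymphocyte, sinusoidal endothelial, erythroid, fetal liver, interferon, p53, stress response and splicing. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and, as alternatives, with a correlation estimated per list and with fry. Counts of members adjusted over the list alone use the Benjamini-Hochberg method within the list.

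Junction usage was tested with diffSpliceDGE of edgeR, with Simes p-values per gene and Benjamini-Hochberg adjustment. Measures of whole libraries were compared with exact two-sided permutation tests, and 3 against 3 libraries allow no p below 0.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

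Genes named in the text were chosen by a rule written before the data were examined. It takes Kdm1a and Yap1 in each comparison, and up to 10 largest rises and 10 largest falls among passing genes whose groups overlap in no library and whose higher group has a mean of at least 50 reads, passing over unnamed models. It further takes the 4 members of each list with the smallest p, for genes shifted back the 10 per direction with the largest smaller change, and for junction usage the 5 genes with the smallest adjusted p. The text names a part of these. Other names were chosen after values were seen, and the text says so.

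The procedure was tested on simulated data made from the counts. With 9 libraries edgeR recovered 40.4% of genes changed 2-fold and 80.6% of genes changed 4-fold, with 3 false among 122 calls. With 6 libraries it recovered 14.3% and 64.6%, with 3 false among 79 calls. Simulated libraries were drawn independently, with the spread estimated from all 9 real libraries. The real libraries may not be independent, and with every replicate 3 left out 0 real genes passed between YAP and WT. These rates of recovery and of false calls may therefore not hold for the real data. A shifted list was found (camera adjusted p = 9.90e-20) with 0 false calls among the other lists. Because simulated genes were drawn independently, this 0 does not cover lists of correlated genes. Other splits of the real libraries gave up to 15 passing lists. Junction usage changes of 4-fold were recovered in 84% of cases with 7 false calls.

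Alternatives fixed before the data were examined were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no filter, at least 50 reads in 3 libraries, unique plus multi-mapped reads, the most read junction of each gene alone, a minimum overhang of 10, the replicate number as a block, only the libraries of the 2 groups compared, a 2-fold minimum and leaving out each library. Scaling by library size alone and leaving out every replicate 3, 1 or 2 were chosen after seeing the data.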

Results

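RNA was sequenced from the livers of mice in 3 groups, with 3 libraries in each. Wild-type mice (WT) were compared with mice carrying an inducible YAP transgene (YAP) and with transgenic mice that also had a knockout of Lsd1 in the liver (YAP_Lsd1ko). YAP is the transcriptional co-activator that the Hippo pathway restrains, and LSD1 is a histone demethylase encoded by Kdm1a. All mice, WT included, had received an AAV8 vector with Cre, and doxycycline in the drinking water (30 mg per L for 14 days) switched the transgene on. The series title places the experiment in work on YAP/TAZ, polyamine metabolism, hypusination of the translation factor eIF5A and LSD1 in proliferation and tumour growth. The measurement was the number of uniquely mapped reads that cross each splice junction, which ranged from 6910297 to 9925154 per library. Reads on annotated junctions of a single gene, 6516711 to 9267028 per library, were summed per gene and are given as CPM after TMM scaling, as mean ± SD over the 3 libraries of a group. The labels do not say whether the 3 libraries of a group came from 3 animals, so all p-values measure only the spread between these libraries. There was no group with the Lsd1 knockout alone, and no interaction of the transgene with the knockout was fitted.

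The targeted gene was read first. Kdm1a (chromosome 4, 136550540 to 136602723, GRCm38) stood at 30.1, 38.3 and 31.3 CPM in WT replicates 1 to 3 and at 36.7, 42.7 and 46.2 CPM in YAP replicates 1 to 3. In YAP_Lsd1ko it stood at 15.8 CPM in replicate 1, at 35.4 CPM in replicate 2 and at 25.3 CPM in replicate 3. The library labelled YAP_Lsd1ko replicate 2 therefore had as much Kdm1a RNA as the WT libraries, and it is named in this way throughout. Kdm1a was 1.65-fold lower in YAP_Lsd1ko than in YAP on average (log2 fold change -0.72, SE 0.25, edgeR adjusted p = 0.186), which did not pass. Against WT it was lower by less and did not pass either (log2 fold change -0.39, SE 0.26, adjusted p = 0.539; -0.14 without YAP_Lsd1ko replicate 1 and -0.69 without the library labelled YAP_Lsd1ko replicate 2). All 16 Kdm1a junctions tested were lower in YAP_Lsd1ko than in YAP and 0 of them passed (edgeR, smallest adjusted p 0.0558), although 5 had an unadjusted p under 0.05. Without the library labelled YAP_Lsd1ko replicate 2, 1 junction passed. A junction that skips an annotated Kdm1a exon had at most 1 read in any library. The labels do not say which part of Kdm1a the knockout allele lacks, and whole liver also holds cells other than hepatocytes.

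Yap1 (chromosome 9, 7931999 to 8004596) was 3.96-fold higher in YAP than in WT, at 74.7 ± 6.89 against 18.9 ± 1.27 CPM (log2 fold change 1.99, SE 0.17, adjusted p = 0.000324). In YAP_Lsd1ko it was lower than in YAP, at 37.8 ± 8.92 CPM (log2 fold change -0.98, SE 0.17, adjusted p = 0.0213), and still above WT (log2 fold change 1.0, SE 0.17, adjusted p = 0.0237). The rise in YAP was carried mainly by 3 of the 9 annotated junctions of the gene, at 8001708 to 8004114, 7973912 to 8001456 and 7953135 to 7962288. These 3 junctions, picked out after their values were seen, summed to 5.46 ± 0.554 CPM in WT, 61.1 ± 5.24 CPM in YAP and 24.5 ± 7.0 CPM in YAP_Lsd1ko. YAP_Lsd1ko had 40.1% of the YAP level there (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). The other 6 junctions of Yap1 had 12.3 ± 1.35, 11.6 ± 0.466 and 11.9 ± 4.14 CPM in WT, YAP and YAP_Lsd1ko. Comparisons between YAP_Lsd1ko and YAP thus set side by side libraries that differed in Yap1 junction reads as well as in the Lsd1 label.

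**Figure D1:**
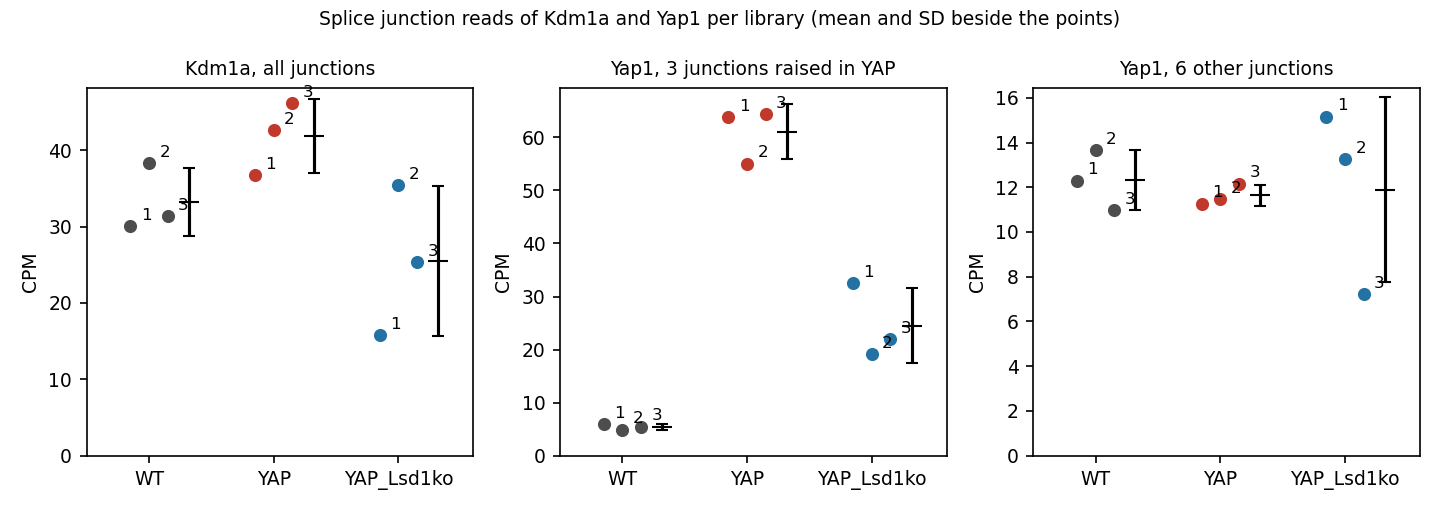
Splice junction reads in CPM for Kdm1a (left), the 3 Yap1 junctions raised in YAP (middle) and the other 6 Yap1 junctions (right), with 1 numbered point per library and the mean and SD of each group beside the points. Kdm1a in the library labelled YAP_Lsd1ko replicate 2 lies at 35.4 CPM, among the WT libraries, and the 3 raised Yap1 junctions of YAP_Lsd1ko lie between WT and YAP.

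The first principal component of log2 CPM took 57.1% of the variance and the second 19.2%. The YAP libraries lay together on the first component, whereas WT and YAP_Lsd1ko libraries were spread along it. The library labelled YAP_Lsd1ko replicate 2 lay at -48.7, among the WT libraries, YAP_Lsd1ko replicate 3 at 1.41 and YAP_Lsd1ko replicate 1 at 31.9, nearest to YAP. In each group replicate 3 lay between replicates 1 and 2.

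**Figure D2:**
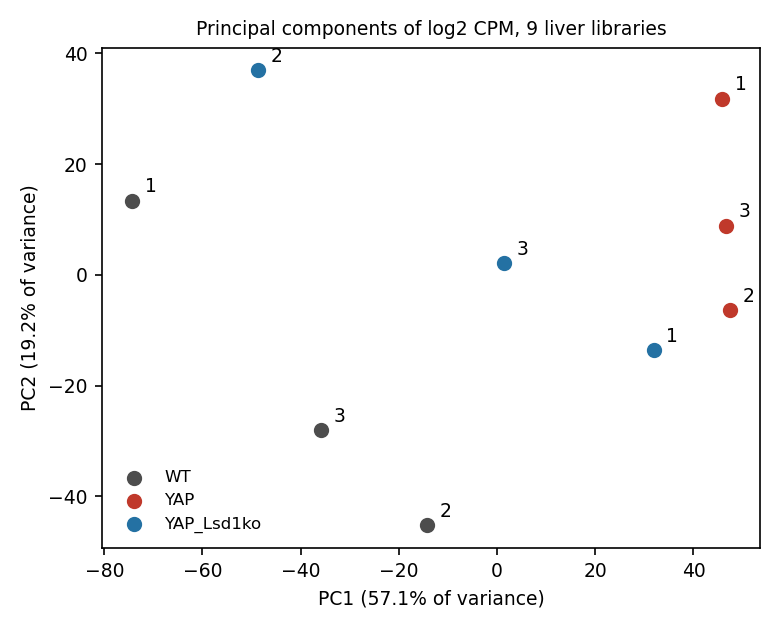
First against second principal component of log2 CPM over the genes tested, 1 numbered point per library, coloured by group. The library labelled YAP_Lsd1ko replicate 2 sits at -48.7 on the first component, on the WT side, and every replicate 3 sits between replicates 1 and 2 of its group.

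Comparison of YAP with WT asks what the transgene changes in liver. In list tests at a preset correlation YAP target genes and biliary and progenitor markers were higher in transgenic livers, and pericentral and mature hepatocyte genes were lower, but with an estimated correlation 0 lists passed (adjusted p = 0.219, 0.219, 0.0973 and 0.264). Keratin 4 (Krt4) and Folh1, the gene of a folate hydrolase, had 474 and 451 reads over the 3 YAP libraries and 0 in WT, so that they were at least 128-fold and at least 122-fold higher (floor of 3 reads over the group). Gpc3, an oncofetal heparan sulphate proteoglycan, rose from 4.56 ± 4.19 to 321 ± 93.6 CPM (69.6-fold, adjusted p = 0.00732). Lgr5 and Notum, Wnt pathway genes of pericentral hepatocytes, fell by 4.33 and 4.24 on the log2 scale (SE 0.42 and 0.43, adjusted p = 0.000505 and 0.000619). Of 10897 genes tested with edgeR, 1901 passed at an adjusted p under 0.05, of which 811 rose and 1090 fell. At least 2-fold changes made up 485 of the rises and 535 of the falls.

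Among the largest changes, Fads3, a fatty acid desaturase, rose from 3.59 ± 1.61 to 171 ± 46.9 CPM (adjusted p = 0.00100). Fam83b had 878 reads in YAP against 1 read in WT, a ratio of 711 with a 95% counting interval of 127 to 28134. The steroid dehydrogenase gene Hsd3b5 had 2133 reads in WT and 0 in YAP and was at least 877-fold lower. Mup7, a major urinary protein gene, fell from 4872 ± 4726 to 0.242 ± 0.212 CPM (adjusted p = 0.00464). Mup genes made up 7 of the 10 largest falls. They are near-identical copies, and their uniquely mapped reads are an uncertain part of their total. By chance alone 10% of comparisons of 3 against 3 libraries do not overlap, and all of these genes met that condition by rule.

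YAP target genes known from other systems rose in 11 of 26 measured members and fell in 0, with 15 that rose and 2 that fell when adjusted over the list alone. Ajuba, a LIM protein that binds the LATS kinases, rose 4.89-fold (log2 fold change 2.29, SE 0.17, adjusted p = 0.000240), the angiomotin relative Amotl2 5.30-fold (adjusted p = 0.00195) and the matricellular factor Ccn2 13.4-fold (adjusted p = 0.00378, named after its value was seen). The list passed as higher (camera adjusted p = 3.03e-08, but adjusted p = 0.219 with an estimated correlation). Hippo pathway components, 7 of which stand on both lists, rose in 8 of 22 members, and 1 of the 8 was Yap1, the gene of the transgene. Adjusted over the list alone 9 rose and 1 fell. The list passed (camera adjusted p = 4.36e-06, but adjusted p = 0.106 with an estimated correlation). Wwc1, an upstream Hippo scaffold, rose 3.46-fold (adjusted p = 0.000855), and Tead1, a DNA-binding partner of YAP, 3.52-fold (adjusted p = 0.00198).

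Biliary and progenitor markers rose in 9 of 22 measured members and fell in 1, likewise 9 and 2 adjusted over the list alone (adjusted p = 3.82e-06, but adjusted p = 0.219 with an estimated correlation). The polycystin gene Pkd2 rose 6.85-fold (SE 0.29 on the log2 scale, adjusted p = 0.000745), the Notch ligand Jag1 3.33-fold (adjusted p = 0.000838) and the fibrocystin gene Pkhd1 5.11-fold (adjusted p = 0.00198). Tff3, a secreted trefoil peptide, was the member that fell (log2 fold change -3.55, named after its value was seen). Fetal liver genes rose in 1 of 6 members, Gpc3 (list adjusted p = 0.0811). S phase and mitosis genes rose in 4 of 41 members, but 1 adjusted over the list alone, and the list passed as higher (adjusted p = 2.76e-05, but adjusted p = 0.531 with an estimated correlation). They included the replication clamp Pcna, 2.06-fold (adjusted p = 0.00664), and the replicative helicase subunit Mcm7, 2.88-fold (adjusted p = 0.0282).

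Pericentral hepatocyte genes fell in 13 of 22 members and rose in 0 (15 fell adjusted over the list alone), with a median log2 fold change of -2.15 (adjusted p = 5.60e-17, but adjusted p = 0.0973 with an estimated correlation). Gulo, the last enzyme of vitamin C synthesis (chromosome 14, 65986786 to 66009207), fell from 1048 ± 37.5 to 95.9 ± 39.3 CPM (adjusted p = 0.000381). Mature hepatocyte genes fell in 10 of 25 members and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 1.26e-08, but adjusted p = 0.264 with an estimated correlation). Transthyretin (Ttr) fell from 5429 ± 686 to 1111 ± 114 CPM and the carboxylesterase Ces3a from 3139 ± 1261 to 162 ± 4.11 CPM. The member that rose was transferrin (Trf, log2 fold change 1.25, named after its value was seen). Periportal genes fell in 7 of 19 members, 9 adjusted over the list alone (adjusted p = 0.000277, but adjusted p = 0.372 with an estimated correlation), among them the urea cycle enzyme Ass1, 3.61-fold lower, and the urocanase Uroc1, 3.09-fold lower.

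Bile acid genes fell in 12 of 25 members and rose in 1 (14 and 1 adjusted over the list alone; adjusted p = 1.31e-05, but adjusted p = 0.219 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 231 ± 38.8 to 62.0 ± 13.7 CPM (adjusted p = 0.00365), the oxysterol hydroxylase Cyp7b1 from 231 ± 128 to 3.99 ± 1.33 CPM (adjusted p = 0.000971), the bile salt export pump Abcb11 3.47-fold and the bile acid uptake transporter Slc10a1 10-fold. Genes of fatty acid and sterol synthesis fell in 7 of 26 members and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 4.36e-06, but adjusted p = 0.234 with an estimated correlation). The elongase Elovl5 fell 3.45-fold (adjusted p = 0.000225), and the sterol enzymes Cyp51 and Hmgcs1 fell 2.68-fold and 3.44-fold. Genes of fatty acid oxidation fell in 9 of 21 members and rose in 1, the pantetheinase Vnn1 at 5.07-fold (12 and 1 adjusted over the list alone; adjusted p = 0.00105, but adjusted p = 0.468 with an estimated correlation). Acaa1b and Ehhadh, enzymes of peroxisomal beta-oxidation, fell 2.80-fold and 2.18-fold.

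Genes of polyamine metabolism and eIF5A hypusination, the subject of the title, moved in both directions: 2 of 18 members rose and 3 fell (3 and 3 adjusted over the list alone). Odc1, the rate-limiting enzyme of polyamine synthesis, rose 1.99-fold (SE 0.15 on the log2 scale, adjusted p = 0.00362). Agmatinase (Agmat, chromosome 4, 141746672 to 141759263) fell from 104 ± 4.72 to 27.6 ± 3.80 CPM (adjusted p = 0.000216), arginase 1 (Arg1) fell 2.73-fold (adjusted p = 0.0279) and the acetyltransferase Sat2 1.92-fold (adjusted p = 0.0189). The list did not pass (adjusted p = 0.842), and its median of 0.005 and mean of 0.08 on the log2 scale were above 0 while the test pointed lower. Of the LSD1 complex list, 1 of 17 members rose, the nucleosome remodelling subunit Mta3 at 1.72-fold (camera adjusted p = 0.343, but fry adjusted p = 0.0259, higher).

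Macrophage and Kupffer cell markers rose in 6 of 19 members and fell in 0 (14 rose adjusted over the list alone), with a median of 1.55 (adjusted p = 4.36e-06, but adjusted p = 0.498 with an estimated correlation). Clec4f, a lectin of Kupffer cells, rose from 171 ± 40.4 to 510 ± 11.3 CPM (adjusted p = 0.0339), and the phagocytic receptor Timd4 from 16.6 ± 3.28 to 54.1 ± 2.67 CPM (adjusted p = 0.0178). Neutrophil markers rose in 3 of 4 members, with S100a8 at 3.46 ± 0.990 against 0.470 ± 0.420 CPM (list adjusted p = 0.00423, but adjusted p = 0.310 with an estimated correlation). Interferon-stimulated genes rose in 1 of 22 members, Ifit2 at 5.73-fold (list adjusted p = 0.00141, but adjusted p = 0.531 with an estimated correlation). Targets of p53 rose in 2 of 16 members, Fas and Btg2, and in 1 adjusted over the list alone (adjusted p = 0.0205, but adjusted p = 0.554 with an estimated correlation). Lymphocyte markers did not pass (1 of 12 rose, Cd3d, and 1 fell, Zap70; adjusted p = 0.15).

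The remaining lists did not pass with camera at the preset correlation. With fry acute phase, sinusoidal endothelial and stress response genes passed as lower (fry adjusted p = 0.0329, 0.0295 and 0.0205). Splicing regulators passed as higher (fry adjusted p = 0.000664). Stellate cell and fibroblast markers had 1 member that rose, the smooth muscle actin Acta2, and 2 that fell, Reln among them, of 21 (adjusted p = 0.161). Of sinusoidal endothelial markers 2 of 17 rose, Cdh5 among them, and 4 fell, Eng among them (adjusted p = 0.316). Acute phase genes rose in 2 of 20 members, ceruloplasmin (Cp) among them, and fell in 5, orosomucoid 1 (Orm1) among them (adjusted p = 0.236). Stress response genes fell in 4 of 16 members, with the transcription factor Xbp1 at 2.08-fold lower, and the list's median of -0.27 and mean of 0.16 differed in sign while the test pointed lower (adjusted p = 0.339). Splicing regulators rose in 3 of 25 members, Qk and Srsf3 among them, and in 0 adjusted over the list alone (adjusted p = 0.0521). Of the erythroid list, 2 members were measured, of which Sptb rose and Alas2 fell (adjusted p = 0.751).

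The count of changed genes rested on replicate 3 of each group, which lay between the other replicates. With every replicate 3 left out, 0 genes passed with edgeR at 6 libraries (1476 at an unadjusted p under 0.05, and 471 passed with DESeq2). Of the 1901 genes 1900 kept their sign, but they had been chosen with these same libraries, so this says little about stability. With 1 library left out, 748 passed without WT replicate 3, 764 without YAP replicate 3, 989 without YAP replicate 1, 1112 without WT replicate 1 and 1196 without YAP replicate 2. Scaling by library size alone, which moved the median of all genes by 0.31 on the log2 scale, turned the split from 42.7% to 75.9% higher.

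**Figure D3:**
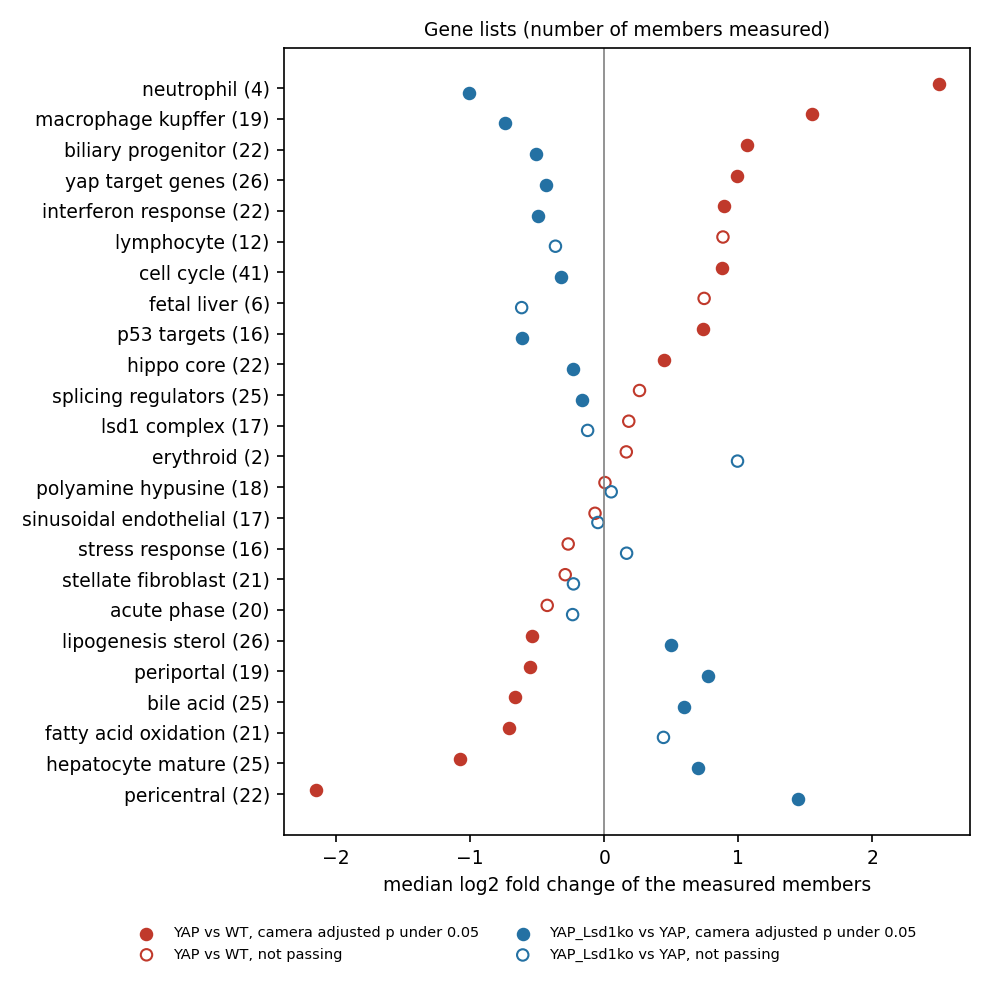
Median log2 fold change of the measured members of each of the 24 gene lists, for YAP against WT and for YAP_Lsd1ko against YAP, with filled points where camera passed at an adjusted p under 0.05 and open points elsewhere; the number measured stands beside each name. The pericentral list has medians of -2.15 and 1.44, and with an estimated correlation 0 lists passed in either comparison.

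Comparison of YAP_Lsd1ko with YAP asks what Lsd1 loss changes in livers with the transgene, with the limit that Kdm1a and Yap1 set above. In list tests at a preset correlation pericentral, mature hepatocyte, bile acid and lipid synthesis genes were higher in YAP_Lsd1ko than in YAP, but with an estimated correlation 0 lists passed (adjusted p = 0.202, 0.308, 0.202 and 0.202). Notum rose from 1.46 ± 1.26 to 10.1 ± 1.25 CPM (adjusted p = 0.0169) and the carboxylesterase Ces3a from 162 ± 4.11 to 1487 ± 663 CPM (adjusted p = 0.00838). Agmat rose 2.33-fold, to 64.3 ± 3.68 CPM (log2 fold change 1.22, SE 0.12, adjusted p = 0.00715). It lies on the chromosome of Kdm1a, within 10 Mb of that gene. Jag1 (chromosome 2, 137081456 to 137116644) fell by 1.34 on the log2 scale (SE 0.19, adjusted p = 0.0118). In total 231 genes passed, of which 191 rose and 40 fell, with 126 and 24 of them changed at least 2-fold.

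The largest rises included the sulfotransferase Sult2a8 (from 13 ± 6.26 to 843 ± 622 CPM, adjusted p = 0.0321), the carboxylesterase Ces3b (24.8-fold, adjusted p = 0.0251), Nat8f5 (from 0.472 ± 0.465 to 12.1 ± 0.517 CPM, adjusted p = 0.00762) and the fatty acid hydroxylase Cyp4a12b (14.9-fold, adjusted p = 0.00838). Ces3a and Ces3b, like the Cyp4a12 genes, have close paralogs that can take part of their reads. Rpl11, a protein of the large ribosomal subunit (chromosome 4, 136028265 to 136053428), had 664 reads in YAP and 0 in YAP_Lsd1ko, at least 211-fold lower, but this rests on 1 junction and not on the whole gene. Its other 3 junctions, with multi-mapped reads, differed by -0.17, -0.09 and -0.11 on the log2 scale. At the junction without reads (136050017 to 136050279) reads that map to several places, which were not counted, were also scarce in YAP_Lsd1ko, at 28, 19 and 16 against 825 to 1114 in the other libraries. Ctps, the enzyme of CTP synthesis, fell 3.38-fold (adjusted p = 0.0164), the matrix protein Efemp1 3.65-fold (adjusted p = 0.0211) and Ogn, osteoglycin, 4.80-fold (adjusted p = 0.00762).

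Pericentral genes rose in 5 of 22 members and fell in 0 (12 rose adjusted over the list alone), with a median of 1.44 (adjusted p = 2.75e-12, but adjusted p = 0.202 with an estimated correlation). Besides Notum, the stem cell receptor Lgr5 rose 7.32-fold (adjusted p = 0.0170), Gulo 3.70-fold (adjusted p = 0.0170) and the calcium-binding enzyme Rgn 2.82-fold (adjusted p = 0.0211). Mature hepatocyte genes rose in 3 of 25 members, 11 adjusted over the list alone (adjusted p = 6.88e-08, but adjusted p = 0.308 with an estimated correlation), namely Ces3a, coagulation factor F7 at 3.01-fold and the glycolate oxidase Hao1 at 3.79-fold. Periportal genes rose in 1 of 19 members, Uroc1 at 2.48-fold, while 8 rose and 2 fell adjusted over the list alone (adjusted p = 0.000687, but adjusted p = 0.349 with an estimated correlation). Bile acid genes rose in 5 of 25 members, 10 adjusted over the list alone (adjusted p = 1.95e-06, but adjusted p = 0.202 with an estimated correlation). They included the nuclear receptor Nr0b2 (9.15-fold, adjusted p = 0.0150), the basolateral transporter subunit Slc51b (3.85-fold, adjusted p = 0.0193), Slc10a1 (8.37-fold, adjusted p = 0.0246) and Cyp7b1 (9.07-fold, adjusted p = 0.0396). Genes of fatty acid and sterol synthesis rose in 5 of 26 members, 10 adjusted over the list alone (adjusted p = 9.45e-08, but adjusted p = 0.202 with an estimated correlation), such as the acetyl-CoA carboxylase Acacb (6.69-fold, adjusted p = 0.0205) and the sterol reductase Dhcr7 (1.73-fold, adjusted p = 0.0441). Genes of fatty acid oxidation had 0 of 21 members past the threshold, 2 higher adjusted over the list alone (adjusted p = 0.0539).

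YAP targets fell in 1 of 26 members, Tead1 at 2.12-fold (adjusted p = 0.0487), and in 4 adjusted over the list alone (adjusted p = 0.000433, but adjusted p = 0.332 with an estimated correlation). Ccn2 was at 24.6 ± 10.3 CPM in YAP and 4.78 ± 2.22 CPM in YAP_Lsd1ko and did not pass (adjusted p = 0.0556). Hippo components fell in 3 of 22 members, Yap1, Tead1 and Amot, and in 4 adjusted over the list alone (adjusted p = 0.000427, but adjusted p = 0.202 with an estimated correlation). Biliary and progenitor markers fell in 1 of 22 members, Jag1, and in 3 adjusted over the list alone (adjusted p = 0.000427, but adjusted p = 0.308 with an estimated correlation). Cell cycle genes passed as a list with 0 of 41 members past the threshold (adjusted p = 0.000996, but adjusted p = 0.597 with an estimated correlation), and Pcna stood at 45.9 ± 3.01 CPM against 73.5 ± 15.9 CPM in YAP (adjusted p = 0.103). The same held for macrophage markers (0 of 19 members, median -0.74, adjusted p = 2.32e-05, but adjusted p = 0.516 with an estimated correlation), neutrophil markers (0 of 4, adjusted p = 0.0122, but adjusted p = 0.346 with an estimated correlation), interferon-stimulated genes (0 of 22, adjusted p = 0.00273, but adjusted p = 0.574 with an estimated correlation), p53 targets (0 of 16, adjusted p = 0.00853, but adjusted p = 0.574 with an estimated correlation) and splicing regulators (0 of 25, adjusted p = 0.0331, but adjusted p = 0.202 with an estimated correlation), all of them lower.

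Of the polyamine and hypusination list, 1 of 18 members rose, Agmat, and the list did not pass (adjusted p = 0.501; median 0.05, mean -0.03, test higher). Of the LSD1 complex list 0 of 17 members passed (list adjusted p = 0.105), with the deacetylase Hdac1 at 8.06 ± 2.15 against 13.6 ± 0.553 CPM (adjusted p = 0.0971). Part of this Hdac1 difference lies in 1 junction with 54 reads in YAP and 0 in YAP_Lsd1ko. That junction took 17.4 ± 0.815% of the gene's reads in YAP, so the difference is not one of the whole gene alone. Stress response genes rose in 2 of 16 members, 5 adjusted over the list alone, with the chaperone Hyou1 at 2.08-fold (adjusted p = 0.0190) and the co-chaperone Dnajb9 at 1.95-fold (adjusted p = 0.0222), and the list did not pass (adjusted p = 0.128; median 0.17, mean -0.05, test higher). Stellate cell markers rose in 1 of 21 members, Reln (list adjusted p = 0.445). Acute phase genes, lymphocyte markers, sinusoidal endothelial markers, erythroid genes and fetal liver genes had 0 members past the threshold (list adjusted p = 0.546, 0.202, 0.666, 0.437 and 0.0972).

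The count was set by single libraries. Without YAP replicate 3 it was 5, without YAP_Lsd1ko replicate 3 it was 30, without YAP replicate 1 it was 41 and without YAP replicate 2 it was 116. Without YAP_Lsd1ko replicate 1, leaving the library labelled YAP_Lsd1ko replicate 2 and replicate 3, it was 844, and without the library labelled YAP_Lsd1ko replicate 2 it was 162. With every replicate 3 left out, 0 genes passed with edgeR (499 at an unadjusted p under 0.05, and 80 with DESeq2). The sign was kept by 231 of 231 genes, which says little because the same libraries had chosen them.

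Genes shifted back were those that passed in both comparisons with opposite signs, which asks how much of the transgene's change was absent in YAP_Lsd1ko, where the Lsd1 label and fewer Yap1 junction reads go together. There were 196, of which 161 were lower in YAP than in WT and higher in YAP_Lsd1ko than in YAP, and 35 were higher and then lower. Rdh16f2, a retinol dehydrogenase family gene, fell from 64.2 ± 8.84 to 1.12 ± 0.35 CPM with YAP and stood at 24.7 ± 14.9 CPM in YAP_Lsd1ko. Cyp2e1, a pericentral cytochrome P450, fell from 6645 ± 3394 to 316 ± 61.5 CPM and stood at 3243 ± 2531 CPM in YAP_Lsd1ko. The interleukin gene Il1b rose from 4.37 ± 2.01 to 22.5 ± 2.43 CPM and stood at 7.51 ± 2.28 CPM in YAP_Lsd1ko, and Ctps went from 23.0 ± 7.34 to 111 ± 5.65 and 32.7 ± 9.98 CPM. Eprn had 3 reads in WT against 375 in YAP, a ratio of 101 with a 95% counting interval of 34.4 to 493, and 31 reads in YAP_Lsd1ko. Among the genes changed by YAP, the median share of the change left in YAP_Lsd1ko was 0.558 (quartiles 0.408 and 0.749) for genes that rose and 0.424 (quartiles 0.241 and 0.608) for genes that fell. Of the 231 genes of the second comparison 2 passed in both with the same sign and 33 passed in it alone.

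Both comparisons used the YAP libraries with opposite signs, so that opposite changes arise without any effect. In 20 simulations of 3 unchanged groups 66.2% of all genes had opposite signs. In 20 further simulations, added after the values were seen, YAP kept its difference from WT and YAP_Lsd1ko was set to the YAP means: 2351 to 2539 genes passed between YAP and WT and 0 to 2 between YAP_Lsd1ko and YAP (edgeR), and 0 were shifted back. There the median share of the change left was 0.936 for genes that rose and 0.932 for genes that fell, so selection and shared libraries alone brought it slightly below 1. These simulations draw independent libraries, which the real ones may not be. Over all genes the correlation of log2 fold changes was -0.76 across genes, which are not independent replicates, against -0.49 simulated, and the covariance was -0.51 against -0.06, a difference of -0.44. Independent lists of these sizes would share 2.98 genes that rose then fell and 19.1 that fell then rose. The YAP libraries were too few to split with 2 in each part, and part of the excess may come from these shared libraries. The count was 4 without YAP replicate 3, 27 without YAP_Lsd1ko replicate 3, 34 without YAP replicate 1, 52 without WT replicate 3, 98 without YAP replicate 2, 126 without the library labelled YAP_Lsd1ko replicate 2 and 694 without YAP_Lsd1ko replicate 1. With every replicate 3 left out it was 0 with edgeR and 69 with DESeq2.

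**Figure D4:**
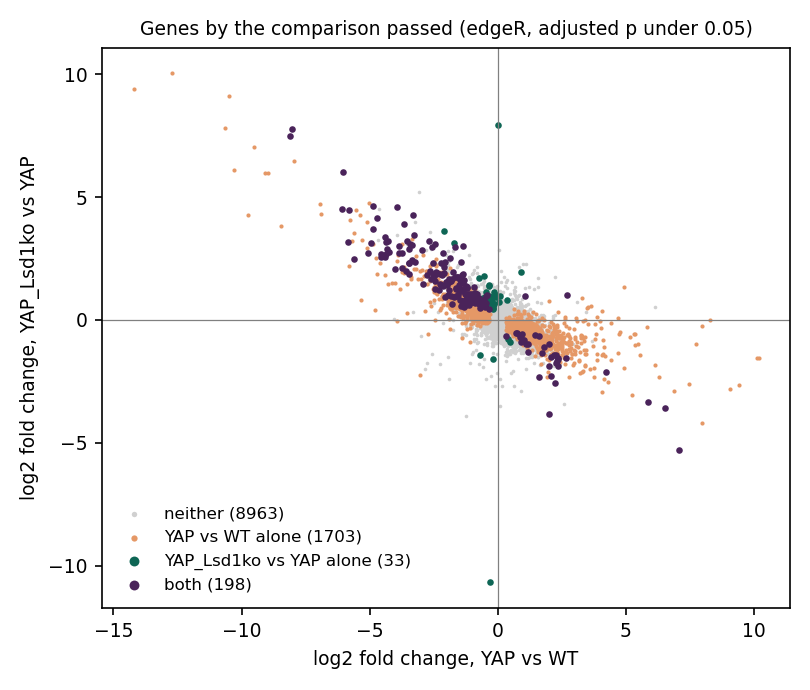
Log2 fold change of YAP against WT (horizontal) and of YAP_Lsd1ko against YAP (vertical), 1 point per gene tested, coloured by the comparison passed with edgeR. Of the 198 genes passing in both, 196 have opposite signs. Opposite signs also arise from the shared YAP libraries, for 66.2% of genes in simulations without any effect. That share is over all genes and not over those passing, so it is no direct counterpart of the 196.

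Comparison of YAP_Lsd1ko with WT asks what differed from wild type in the libraries with both labels, of which the library labelled YAP_Lsd1ko replicate 2 had Kdm1a at WT level. YAP targets were higher in 6 of 26 members and 8 adjusted over the list alone. Hippo components were higher in 3 of 22, Yap1 among them, and 5, and biliary markers in 3 of 22 and 7 with 1 lower. These lists passed (adjusted p = 8.14e-07, 0.00128 and 0.000615), but not with an estimated correlation (adjusted p = 0.371, 0.349 and 0.431). Pericentral genes were lower in 3 of 22 members, 9 adjusted over the list alone (adjusted p = 3.74e-10, but adjusted p = 0.349 with an estimated correlation), namely Oat, Gulo and Lhpp, named after their values were seen. Mature hepatocyte genes were lower in 2 of 25 members, with 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.00128, but adjusted p = 0.632 with an estimated correlation). In total 223 genes passed, of which 122 rose and 101 fell, with 86 and 61 of them changed at least 2-fold.

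Further lists that passed were cell cycle genes (0 of 41, higher, adjusted p = 0.00651, but adjusted p = 0.777 with an estimated correlation), macrophage markers (0 of 19, higher, adjusted p = 0.0128, but adjusted p = 0.777 with an estimated correlation) and genes of fatty acid oxidation (1 rose and 1 fell of 21, lower, adjusted p = 0.00899, but adjusted p = 0.632 with an estimated correlation). Acute phase genes (1 of 20 fell, adjusted p = 0.0178, but adjusted p = 0.371 with an estimated correlation) and stellate cell markers (0 of 21, lower, adjusted p = 0.00330, but adjusted p = 0.678 with an estimated correlation) passed too. Of the polyamine list Odc1 rose and Agmat fell of 18 members, and the list did not pass (adjusted p = 0.722; median -0.01, mean 0.05, test higher). Bile acid genes had 1 member that rose and 1 that fell of 25 (adjusted p = 0.0660), and lipid synthesis genes 3 of 26 that fell (adjusted p = 0.217; median 0.08, mean 0.02, test lower). Periportal genes, the LSD1 complex, neutrophil, lymphocyte and endothelial markers, erythroid and fetal liver genes, interferon-stimulated genes, p53 targets, stress response genes and splicing regulators had 0 members past the threshold and did not pass (adjusted p from 0.0618 to 0.813).

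The count was 32 without WT replicate 3, 41 without YAP_Lsd1ko replicate 3, 111 without WT replicate 2, 117 without YAP_Lsd1ko replicate 1, 136 without WT replicate 1 and 614 without the library labelled YAP_Lsd1ko replicate 2. With every replicate 3 left out 0 genes passed with edgeR (481 at an unadjusted p under 0.05, and 73 with DESeq2). The sign was kept by 223 of 223 genes, which again had been chosen with the same libraries. Scaling by library size alone, which moved the median of all genes by 0.17 on the log2 scale, turned the split from 54.7% to 76.2% higher.

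Junction usage, the share of a gene's reads taken by each of its junctions, was tested in 7791 genes with 73170 junctions. It changed in 9 genes between YAP and WT, in 3 between YAP_Lsd1ko and YAP and in 4 between YAP_Lsd1ko and WT (edgeR diffSpliceDGE, Simes adjusted). A junction of Scp2, the sterol carrier protein (chromosome 4, 108055569 to 108063885), took 0.961 ± 0.202% of the gene's reads in WT, 8.06 ± 1.69% in YAP and 2.19 ± 0.470% in YAP_Lsd1ko (adjusted p = 1.98e-07 for YAP against WT). It had 1001 reads in WT, 1133 in YAP and 1440 in YAP_Lsd1ko, so between WT and YAP its share moved mostly with the other junctions of the gene. A junction of the RNA-binding protein gene Rbm26 (chromosome 14, 105117100 to 105120981) rose from 6.08 ± 1.39% to 21.6 ± 0.221% in YAP (adjusted p = 0.000567), and 1 of the oxysterol-binding protein gene Osbpl9 from 0.730 ± 0.286% to 3.0 ± 0.399% (adjusted p = 2.85e-06). Ndrg2 (adjusted p = 0.00241) and Yap1 (adjusted p = 3.17e-05) were the other 2 of the 5 genes with the smallest adjusted p. Yap1 is the gene of the transgene, and 3 of its junctions rose from 5.46 to 61.1 CPM in YAP. Its other 6 junctions stood at 12.3 CPM in WT and 11.6 CPM in YAP. The Yap1 calls, here and between YAP_Lsd1ko and WT, therefore do not by themselves show changed splicing.

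Between YAP_Lsd1ko and YAP the genes were Hdac1, Rbbp4 and Scp2. The Hdac1 junction at chromosome 4, 129523102 to 129524245, had 26 reads in WT, 54 in YAP and 0 in YAP_Lsd1ko (11.1 ± 2.05% and 17.4 ± 0.815% of the gene in WT and YAP, adjusted p = 1.38e-05). The Rbbp4 junction at chromosome 4, 129317920 to 129318443, fell from 9.0 ± 0.597% to 3.22 ± 0.717% (adjusted p = 0.00182). Hdac1 and Rbbp4 encode subunits of the same deacetylase complexes, and all 3 genes, Scp2 included, lie on the chromosome of Kdm1a. Between YAP_Lsd1ko and WT the genes were Hdac1, Yap1, Pqlc1 (4.47 ± 1.35% against 15.8 ± 4.27%, adjusted p = 0.00400) and the sialyltransferase St6gal1, with 39 reads in WT and 1 in YAP_Lsd1ko at its junction (adjusted p = 0.0130). With every replicate 3 left out 0 genes passed in each comparison (68, 35 and 56 had an unadjusted p under 0.05 with 9 libraries, and limma called 7, 2 and 6). Between YAP and WT 3 passed without WT replicate 3, 4 without YAP replicate 1 and 5 without YAP replicate 3. Between YAP_Lsd1ko and YAP 0 passed without YAP_Lsd1ko replicate 3 and 1 without YAP replicate 1 or 3. Between YAP_Lsd1ko and WT 0 passed without WT replicate 3 or YAP_Lsd1ko replicate 3 and 2 without WT replicate 1 or 2.

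Measures of the libraries as a whole were compared with exact permutation tests, which at 3 against 3 libraries cannot pass the threshold. Unannotated junctions took 0.902 ± 0.0470% of junction reads in WT, 0.912 ± 0.0818% in YAP and 0.938 ± 0.0290% in YAP_Lsd1ko. After thinning to 6910297 reads, 98727 ± 4880, 106289 ± 2878 and 102150 ± 6183 junctions had 3 or more reads, and all 3 YAP libraries (103886 to 109479) lay above all 3 WT libraries (93456 to 103087; p = 0.1, exact two-sided permutation test). The 10 most counted genes took 25.2 ± 2.0%, 28.6 ± 1.74% and 23.8 ± 3.61% of gene reads. In 9 exact two-sided permutation tests p was 0.1 to 0.9, where 0.1 is the smallest possible, and the adjusted p was 0.6 or more.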

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

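The patterns in this part were found in the data, and the tests of a separate animal, of the transgene level, of genes outside both other groups, of whole-gene expression and of a minimum of 5 reads were chosen after the results were seen.

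Among junctions outside the annotation, which the comparisons did not use, 4 had 10 or more reads in every YAP library and 0 in all WT libraries. They included 1 in Fam83b (chromosome 9, 76545844 to 76581563, with 95, 22 and 45 reads) and 1 in Nrg1 (chromosome 8, 31838329 to 31849309, with 13, 10 and 14 reads). The other 2 lay at chromosome 1, 186589588 to 186589804, and chromosome 19, 5796144 to 6609385. Their splice sites could not be assigned to exactly 1 annotated gene, which does not mean that no gene lies there. Reads on annotated junctions shared by several genes, which were left out of gene counts, took 7.92 ± 0.677% in YAP against 3.46 ± 0.0217% in WT and 5.64 ± 0.966% in YAP_Lsd1ko, and 83.3% of them lay on 14 junctions of transferrin (Trf).

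In each group replicate 3 lay between replicates 1 and 2, for 1652 of the 1653 genes in which replicates 1 and 2 differed 2-fold. A merging of the reads of replicates 1 and 2 is argued against by unannotated junctions found in replicate 3 alone, up to 1.34 times as many as in replicates 1 and 2. Preparation of replicate 3 from RNA of replicates 1 and 2 together stays open: genes with replicate 3 outside both others by 1.5-fold were at most 0.0277 times as many as for the other replicates, but this partly restates the pattern. A separate animal that lies midway cannot be told apart from it, because without technical replicates no bound can be set for the distance from the best mixture. The median squared distance was 1.31, 2.33 and 3.47 times that of counting noise in WT, YAP and YAP_Lsd1ko. This unit takes each read as counted once, although a read that crosses several junctions is counted at each. The best mixture gave replicate 1 a weight of 0.47, 0.46 and 0.49, and pooling in equal parts would give such near-equal weights. No biological explanation was tested, and if replicate 3 holds RNA of the other 2, each group has 2 independent samples.

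Genes shifted back in YAP_Lsd1ko, 196 against at most 1 in other splits of the libraries, set a loss of LSD1 beside a lower level of the transgene. Of 100 drawn splits of the 9 libraries into 3 groups 1 gave as many, the real one, but such splits also undo the change from WT to YAP and do not test the step from YAP to YAP_Lsd1ko. Lower transgene expression cannot be told apart from Lsd1 loss, because the Yap1 junctions that rise with the transgene stood at 40.1% of the YAP level in YAP_Lsd1ko. Genes that passed against both other groups with the same sign numbered 14, such as Cyp3a59 (CPM 23.9 in WT, 156 in YAP and 317 in YAP_Lsd1ko) and Fgl1 (470, 411 and 137). They do not decide on lower transgene expression, because both comparisons share the YAP_Lsd1ko libraries and no count without an effect was simulated. Whether each gene responds steadily to the transgene level was not tested either. Of these 14 genes Rpl11 rests on 1 junction, and it and Cep85 lie within 10 Mb of Kdm1a. The library labelled YAP_Lsd1ko replicate 2, with Kdm1a at WT level, had the lowest level of these Yap1 junctions, 19.2 CPM, and lay nearest WT (0.189 between WT at 0 and YAP at 1), while replicate 1, with the least Kdm1a, lay nearest YAP (0.727).

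Of 49212 annotated splice junctions with 10 or more reads in all WT and YAP libraries, 1 had 0 reads in YAP_Lsd1ko. It lay in Rpl11, 0.526 Mb from Kdm1a, and 691 of the 49212 (1.40%) lay within 10 Mb of Kdm1a. The Fisher exact p of 0.0140 only restates this share. It is no test of clustering, because it rests on 1 junction already seen among the largest falls. With a minimum of 5 reads 2 junctions had no reads in YAP_Lsd1ko, in Rpl11 and Hdac1, both near Kdm1a. In WT and YAP 7 and 5 junctions were missing, 0 of them near. Lower expression of the whole gene is argued against for Rpl11 by its other 3 junctions, with a median log2 change of -0.11, and for Hdac1 by the junction's share of the gene's reads, 17.4 ± 0.815% in YAP (54 reads) and 0% in YAP_Lsd1ko (0 reads). The requirement of 0 reads left out a St6gal1 junction on chromosome 16, with 39 reads in WT, 24 in YAP and 1 in YAP_Lsd1ko. It also left out the Rbbp4 junction on chromosome 4, which kept 156 reads in YAP_Lsd1ko. Sequence of another strain around Kdm1a, carried with the allele, stays open: 100% of the junctions without reads lie within 10 Mb, but they are too few. An effect of LSD1 on these junctions was not tested.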

How the results depend on the processing

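Leaving out every replicate 3, 1 or 2, DESeq2 on 6 libraries and scaling by library size alone were chosen after seeing the data; all other alternatives were planned. DESeq2 size factors, no filter, a stricter filter, multi-mapped reads and a minimum overhang left every count of changed genes within 1.5 times. The cause of the changes below was not tested, except that a 2-fold minimum lowers counts by construction. Depth and spread limit the detection of small changes, with 40.4% of genes changed 2-fold recovered in simulated data. Those data were drawn as independent libraries, which the real ones may not be. Of 3339 values of named genes under alternatives, 2631 kept direction and side of the threshold, 683 lost it, 24 gained it and 1 turned, and of 864 values of lists 722, 86, 41 and 15. The 2-fold minimum does not alter the test of a single gene. Its 88, 54 and 18 values for YAP against WT, YAP_Lsd1ko against YAP and YAP_Lsd1ko against WT were therefore kept by construction.

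Against 1901 genes for YAP against WT, counts were 748 to 1709 leaving out 1 library, 0, 1232 and 2354 without every replicate 3, 1 and 2, 1020 with a 2-fold minimum, 471 with DESeq2 on 6 libraries, 1105 with the most read junction and 2545 by library size. Against 231 for YAP_Lsd1ko against YAP they were 5 to 844 leaving out 1 library, 0 without replicate 3, 919 without replicate 1, 150 with a 2-fold minimum, 712 with DESeq2, 80 with DESeq2 on 6 libraries, 146 by library size and 109 with only the 2 groups. Against 223 for YAP_Lsd1ko against WT they were 32 to 614 leaving out 1 library, 0 without replicate 3, 804 without replicate 2, 147 with a 2-fold minimum, 597 with DESeq2, 73 with DESeq2 on 6 libraries, 114 with the most read junction and 83 with only the 2 groups. Against 196 genes shifted back they were 4 to 694 leaving out 1 library, 503 without replicate 1, 0 without replicate 3, 129 with a 2-fold minimum, 587 with DESeq2, 69 with DESeq2 on 6 libraries and 127 by library size.

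With the replicate number as a replicate block, counts were 1027, 46, 89 and 41 in the same order, and junction usage between YAP and WT gave 5 genes. The numbers do not pair samples, and not every library correlated best with its own number.

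Lists passing numbered 14, 14 and 10 in the order YAP against WT, YAP_Lsd1ko against YAP and YAP_Lsd1ko against WT. With an estimated correlation 0, 0 and 0 passed. With fry 15 passed for YAP against WT (6 higher and 9 lower), where 4 lists lost and 5 gained their call. For YAP_Lsd1ko against YAP 7 passed with fry, the LSD1 complex and stress response among them, and for YAP_Lsd1ko against WT 0. The LSD1 complex passed there as lower (fry adjusted p = 0.0240), and its list holds the targeted gene Kdm1a as well as Hdac1. Leaving out 1 library gave 5 to 16 for YAP_Lsd1ko against WT. Directions that turned belong to lists that did not pass with all 9 libraries. By library size these were erythroid genes (adjusted p = 0.924) and polyamine genes (0.928) for YAP against WT, and the LSD1 complex and stress response (both 0.981) for YAP_Lsd1ko against WT, and without every replicate 3 polyamine genes for YAP against WT (0.970). Leaving out 1 library turned further lists, at adjusted p from 0.483 to 0.982 where they turned; with the range over all libraries left out in turn, these were erythroid genes for YAP against WT (0.530 to 0.839), and for YAP_Lsd1ko against YAP lymphocyte (0.0369 to 0.814), endothelial (0.518 to 0.891) and stellate markers (0.0275 to 0.982). For YAP_Lsd1ko against WT they were interferon (3.40e-05 to 0.717), lipid synthesis (0.0249 to 0.951), lymphocyte (0.0249 to 0.717) and p53 genes (0.0351 to 0.719). Kdm1a in YAP_Lsd1ko against WT turned with its most read junction alone (log2 fold change 0.00149).

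Junction usage changed in 9, 3 and 4 genes. Without every replicate 3 the counts were 0, 0 and 0, and with unannotated junctions 17, 5 and 8. For YAP_Lsd1ko against WT the gene-level test gave 10 and the stricter filter 1. Leaving out 1 library gave 3 to 6, 0 to 3 and 0 to 4, and for Kdm1a junctions 0 to 1.

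Of library measures, unique plus multi-mapped reads changed the junctions with 3 or more reads after thinning (25960 for YAP against WT, -17046 for YAP_Lsd1ko against YAP), the share of the 10 most counted genes (-10.7 and 7.16) and the unannotated share (0.375 and -0.282, and 0.0927 for YAP_Lsd1ko against WT). With a minimum of 3 reads the unannotated share differed by -0.0250 for YAP against WT. Leaving out 1 library gave -0.0319 to 0.0498 for that share in YAP against WT, -0.0132 to 0.0685 in YAP_Lsd1ko against YAP, and -3.34 to 0.238 for the top 10 share in YAP_Lsd1ko against WT.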

Other observations

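The lists of sex-biased liver genes were chosen after some of their members were seen among the largest changes, as were the genes named here, so no test of these lists is given.

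Male-biased liver genes fell with YAP in 17 of 19 members, with a median log2 fold change of -3.53, and rose in YAP_Lsd1ko against YAP in 9 of 19, with a median of 2.64. The antitrypsin gene Serpina1e went from 4807 to 97.7 and 545 CPM and the fatty acid hydroxylase Cyp4a12a from 405 to 75.1 and 643 CPM in WT, YAP and YAP_Lsd1ko. Female-biased genes rose with YAP in 6 of 14 measured members and fell in 2, with a median of 0.37, and fell in YAP_Lsd1ko against YAP in 4, with a median of -1.46. The monooxygenase Fmo2 went from 14.9 to 76.5 and 26.1 CPM, and the transcription factor Cux2, which is active in female liver, rose with YAP (log2 fold change 4.22) and fell in YAP_Lsd1ko against YAP (log2 fold change -2.11). Against WT, YAP_Lsd1ko had 3 male-biased genes lower, with a median of -0.80, and 1 female-biased gene higher and 1 lower. The Y-linked genes Ddx3y (925 to 1553 reads) and Eif2s3y (682 to 1429 reads) were read in every library and Xist had at most 1 read, so the libraries did not differ in sex.

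Multi-mapped junction reads ranged from 1307900 to 17284000 per library (rounded to 6 digits). The Mup cluster of chromosome 4 took 92.7, 66.6 and 87.9% of them in WT, 1.44, 5.94 and 4.03% in YAP and 52.9, 88.4 and 82.2% in YAP_Lsd1ko.

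Between WT at 0 and YAP at 1, over the 1020 genes changed at least 2-fold, YAP_Lsd1ko replicate 1 lay at 0.727, the library labelled YAP_Lsd1ko replicate 2 at 0.189 and replicate 3 at 0.491.

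With 3 against 3 libraries there are 10 splits, too few to exclude chance. The real count and the highest of the other splits were 1901 and 0 genes for YAP against WT, 231 and 0 for YAP_Lsd1ko against YAP, and 223 and 0 for YAP_Lsd1ko against WT, with 1 split as large in each. For lists they were 14 and 15, 14 and 15, and 10 and 14, with 2, 4 and 5 splits as large. For junction usage they were 9 and 0, 3 and 0, and 4 and 0 genes, with 1 split as large in each.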
